A study of Mus musculus with 8 samples.

How the data were processed

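RNA from mouse 3134 mammary cells was measured on 8 oligonucleotide arrays, 2 in each of 4 groups. The groups cross 0 h and 4 h of dexamethasone (100 nM) with the tetracycline state given in the sample titles. Per the labels' protocols, cells were kept in charcoal-treated serum for 48 h before hormone, and tetracycline was used at 1 ug per ml. The deposited table holds log2 expression values from the authors for 28888 probe sets on 8 sample columns. Per the submitters' processing notes, Affymetrix Expression Console and RMA (background correction, quantile normalization and summary of probes per probe set) were used; versions are not given in the sources used here. RMA makes the arrays' distributions alike, so a change shared by most genes cannot be seen in these values, and small folds of dim genes are compressed.

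Groups follow the titles and the matching tetracycline characteristic. The treatment protocol text states the opposite tetracycline state for each of the 8 samples, so the arms are named here by their titles, as the no-titled arm and the plus-titled arm, and which of them expressed A-fos is not settled by the labels. Nothing in the labels says that the 2 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

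Probe sets were named through the array's annotation, with gene symbols looked up by gene number in a RefSeq mouse gene table used for names only. Exactly 1 symbol was given for 21789 probe sets, several for 1621 and none in the table used for 5478. Of the symbols, 21698 were found by gene number. Among probe sets with 1 symbol, that with the highest mean over the 8 arrays stood for its gene, which left 19938 genes; 999 genes had more than 1 probe set. No filter on signal was applied. The number of arrays limits the precision, and no genome positions were used here.

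Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single model with a mean per group over all 8 arrays, 2-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. The model had 4 residual degrees of freedom, and the prior added 6.64 with a prior SD of 0.127. All adjusted p-values of genes below are from this limma model unless another is named. The contrasts were the dexamethasone response in each arm, the difference between the arms (plus-titled minus no-titled) at 0 h and at 4 h, and the difference of the 2 responses. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists within each contrast. Camera with a correlation estimated from the data, and fry, were run as alternatives.

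The 22 lists were fixed before the data were examined. They cover glucocorticoid-induced genes, inflammatory mediators, AP-1 subunits, AP-1 target genes, immediate-early genes, MAPK feedback genes, G1/S and G2/M cell cycle genes, extracellular matrix genes, YAP-TEAD target genes, circadian clock genes, interferon-stimulated genes, integrated stress response genes, cholesterol synthesis genes, the glucocorticoid receptor with its cofactors and chaperones, milk protein genes, and markers of luminal, basal, adipocyte, leukocyte, endothelial and pituitary corticotroph cells. Of 363 list members, 333 were matched to a tested gene. Named genes were chosen by a rule also fixed beforehand: the 10 largest called changes in each direction with non-overlapping groups, up to 4 called members of each list with the largest change or, with none called, up to 2 with the smallest p, and Fos, Fosl1, Jun and Nr3c1 in every case. Where fewer than 5 genes passed, the 10 with the smallest p were named. Genes known only by a clone or accession were counted and not named.

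The procedure was tested on simulated data with the real means of 19938 genes. Spreads were drawn at random from the model's fitted prior, not taken from each gene, and noise was independent between genes. In each contrast 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, fewer than differed between the arms, so recovery in the real data may differ. In the no-titled arm's response, 32.8% of genes changed 1.5-fold, 91% of those changed 2-fold and 100% of those changed 4-fold were called. The difference of the responses recovered 1.5%, 56.7% and 98.5% at those sizes, or 1, 38 and 65 genes. Unchanged genes called falsely numbered 9 in that contrast and 5 to 11 in the others. Alternatives were another variance model, only the arrays compared, the replicate number as a block, a filter on dim genes, median centring, cyclic loess, other probe set rules, a 2-fold minimum, and each array left out in turn. An adjustment of the difference of responses over the responding genes alone was added after the data were seen.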

Results

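The data describe gene expression in 3134 cells, a mouse mammary line derived from C127, that carry A-fos under a Tet-Off switch. A-fos is a dominant negative protein that keeps AP-1, the dimer of Fos and Jun family proteins, from binding DNA. The study asked how the response to dexamethasone, a synthetic ligand of the glucocorticoid receptor, depends on AP-1 binding. Each of the 4 groups (0 h or 4 h of 100 nM dexamethasone, in 2 arms) had 2 arrays. The titles and the treatment protocols give opposite tetracycline states for every sample. Arms are therefore called no-titled and plus-titled, after the titles, and signs below carry no statement about which arm expressed A-fos.

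Array medians lay between 5.36 and 5.47 on the log2 scale, the lowest being replicate 1 of the untreated plus-titled group. Replicates correlated at 0.9932 to 0.9956 across genes, and 4 to 24 genes differed more than 2-fold within a pair, the most in the untreated plus-titled group. The first principal component (43.8% of the variance) separated the arms and the next (21.5%) separated 0 h from 4 h. The component after those (9.7%) set the 2 untreated plus-titled arrays apart, at 17.63 and -15.29. Signal of the Fos probe set was 5.03 ± 0.10 and 5.35 ± 0.22 (log2, SD, n = 2) at 0 h in the no-titled and plus-titled arms, a difference of 0.31 that did not pass (adjusted p = 0.18). At 4 h it was 5.36 ± 0.03 and 6.07 ± 0.11, higher in the plus-titled arm by 0.71 ± 0.13 (SE, adjusted p = 0.00685), a call lost without replicate 1 of the treated plus-titled group (0.64, adjusted p = 0.053). Whether that probe set reads the A-fos transgene is not known here, so it does not check the labels.

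In the no-titled arm, 4 h of dexamethasone raised genes of the classical glucocorticoid response. Mt2, a metallothionein, rose by 3.89 ± 0.22 (log2, SE) and Lcn2, an iron-carrier binding protein, by 3.40 ± 0.15. Fkbp5, a co-chaperone of the receptor, rose 8.27-fold (log2 3.05 ± 0.12, adjusted p = 6.16e-07), and Tsc22d3, which encodes the leucine zipper protein GILZ, rose by 2.64. Suox, which encodes sulfite oxidase, rose by 3.21 and the acute-phase gene Orm3 by 3.26. Orm1 and Orm3, like Mt1 and Mt2, are close relatives whose probes can read each other. The urokinase gene Plau fell by 1.70 ± 0.13, Phlda1 fell by 1.49, the kinase gene Plk2 fell by 1.36 and Thbs1, which encodes thrombospondin, fell by 1.34.

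Of 29 measured glucocorticoid-induced genes in this arm, 19 rose, 0 fell and 10 did not pass. Adjusted over the list alone, 22 rose. Their median was 1.63 (camera adjusted p = 7.56e-55, and adjusted p = 0.0124 with an estimated correlation). Of 18 AP-1 target genes, 3 fell and 15 did not pass, with 6 lower when adjusted over the list alone. Plau and its receptor gene Plaur (log2 -1.20) were among those that fell. The list's camera adjusted p was 7.66e-05, and it was lost at adjusted p = 0.0909 with an estimated correlation. Of 25 inflammatory mediators, 4 fell, with 1 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.0077, and adjusted p = 0.337 with an estimated correlation). Cxcl5 at -0.92 was the largest of these. Over the 8 fits without 1 array between 0 and 4 were called, and without replicate 2 of the untreated group all 4 were lost (Cxcl5 -0.76, adjusted p = 0.0914, Ptgs2 -0.90, 0.0817, Ccl2 -0.61, 0.316, and Irf1 -0.56, 0.241). Cxcl5 was lost in 2 of these fits, Ptgs2 and Irf1 in 4 each and Ccl2 in 6, and with the mean of its probe sets Irf1 had adjusted p = 0.232. Of 16 integrated stress response genes, 1 fell and 15 did not pass, with 2 lower when adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.945 with an estimated correlation). That member, Ddit3 at -0.69, was lost without any 1 of this arm's own 4 arrays (adjusted p between 0.0619 and 0.141). Of the glucocorticoid-induced genes 18 to 20 were called over the 8 fits, and of the AP-1 target genes 2 to 3. The AP-1 subunit gene Fosl2 fell by 0.91, the 1 called of 15 AP-1 subunit genes, with 3 lower when adjusted over the list alone (camera adjusted p = 0.838). Jun at -0.55 (adjusted p = 0.0569), Fos at 0.32 (0.454), Fosl1 at -0.50 (0.241) and the receptor gene Nr3c1 at -0.38 (0.144) did not pass. The clock genes Per1 and Nfil3 rose by 1.90 and 1.58, and they were the 2 members called of 16, with 2 higher and 3 lower when adjusted over the list alone. The matrix gene Postn rose by 1.61, and Fabp4, an adipocyte marker, rose by 1.68. Neither list moved as a set. Of 21 matrix genes, 2 rose and 1 fell, Thbs1, with 4 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.931). Fabp4 was the 1 called of 7 adipocyte markers, also when adjusted over the list alone (camera adjusted p = 0.803).

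Over all 19938 genes, limma called 285 in the no-titled arm, 205 higher and 80 lower, of which 88 rose and 10 fell at least 2-fold. Without any 1 of this arm's own 4 arrays, between 134 and 143 genes were called, of which only 21 or 22 were lower. Trend and robust variance gave 297 higher and 164 lower.

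Dexamethasone raised glucocorticoid-induced genes in the plus-titled arm as well. Lcn2 rose by 4.22 ± 0.15 (log2, SE), Mt2 by 3.98, the kinase gene Sgk1 by 3.38, Fkbp5 by 3.32 (9.99-fold, adjusted p = 2.02e-07) and Glul, which encodes glutamine synthetase, by 3.02. Plau fell by 1.57, Thbs1 fell by 1.56, Pcdh18 fell by 1.48 and the protease gene Adamts1 fell by 1.47. Fhl2, a LIM domain gene, fell by 1.22. The matrix crosslinking gene Lox rose by 1.27 and Ccn2 by 1.28. Of 21 matrix genes, 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.661).

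Glucocorticoid-induced genes again rose, with 20 of 29 higher, 0 lower and 9 not passing, and 23 higher when adjusted over the list alone. Their median was 1.51 (camera adjusted p = 7.64e-53, and adjusted p = 0.0133 with an estimated correlation). Of 18 AP-1 target genes, 2 fell, Plau and Plaur, with 3 lower when adjusted over the list alone (camera adjusted p = 0.000984, and adjusted p = 0.159 with an estimated correlation). The call of Plaur at -0.82 was lost in 2 of the fits without 1 array (adjusted p up to 0.158). Of 25 inflammatory mediators, 2 fell, with 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0467, and adjusted p = 0.529 with an estimated correlation). Both of these, Ccl2 at -0.90 and Irf1 at -0.82, were lost in 3 of the 8 fits without 1 array, those without replicate 1 of the untreated group or either treated array of this arm (adjusted p up to 0.143 and 0.0583). None of 15 cholesterol synthesis genes was called singly, although all 15 were below 0, with a median of -0.20 (camera adjusted p = 0.00016, and adjusted p = 0.529 with an estimated correlation). Adjusted over the list alone, 3 of them were lower. The G1/S genes, with 0 called of 20 and 0 when adjusted over the list alone, had a median of -0.22 (camera adjusted p = 0.0017, and adjusted p = 0.64 with an estimated correlation). Of 12 MAPK feedback genes, Phlda1 fell by 1.18 and 11 did not pass, with 3 lower when adjusted over the list alone (camera adjusted p = 0.0041, and adjusted p = 0.529 with an estimated correlation). Integrated stress response genes had a camera adjusted p of 0.00471 and adjusted p = 0.529 with an estimated correlation, with 1 member lower of 16, and with 1 higher and 3 lower when adjusted over the list alone. That member, Trib3 at -0.65, was lost in 6 of the 8 fits (adjusted p up to 0.352) and in 3 other settings (up to 0.0778). Of the glucocorticoid-induced genes 17 to 20 were called over the 8 fits, and of the AP-1 target genes 1 to 2. Per1 and Nfil3 rose by 1.82 and 1.51. Of 15 AP-1 subunit genes, Fos rose by 0.73 ± 0.13 (adjusted p = 0.0236) and Jun fell by 0.70 ± 0.12 (adjusted p = 0.0188), as they did when adjusted over the list alone (camera adjusted p = 0.805). Without replicate 1 of the untreated group both calls were lost (Fos 0.57, adjusted p = 0.153, and Jun -0.61, adjusted p = 0.144), as they were without replicate 2 of the treated group (0.80, adjusted p = 0.101, and -0.59, adjusted p = 0.201). That of Fos was also lost without replicate 1 of the treated group (0.65, adjusted p = 0.163). With only the 4 arrays of this arm, Fos had adjusted p = 0.0611 and Jun 0.0594. Fosl1 at -0.20 (adjusted p = 0.749) and Nr3c1 at -0.48 (adjusted p = 0.0606) did not pass. The difference of the responses was not called for Fos (0.40, adjusted p = 0.967), Jun (-0.15, adjusted p = 0.997), Fosl1 or Nr3c1.

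In total limma called 220 genes in the plus-titled arm, 164 higher and 56 lower, of which 61 rose and 8 fell at least 2-fold. Without any 1 of this arm's own 4 arrays, between 80 and 129 were called, with 12 to 31 lower. Trend and robust variance gave 249 higher and 121 lower, and leaving out the dimmest genes 234 and 123.

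The 2 responses shared 105 genes that rose and 22 that fell, against 1.69 and 0.225 for independent lists, and 0 genes were called in opposite directions. These responses share no arrays. Over the 285 genes of the no-titled arm, the slope of the plus-titled response on the no-titled one was 0.746, with an SD of 0.0399 over 16 choices of single arrays, and 271 genes had the same sign. The slope over the 220 genes of the plus-titled arm was 0.89 (SD 0.0499) for the opposite regression, and 215 genes had the same sign. The 16 choices recombine the same arrays that were used to call the genes. They are not independent, and their SD is not a sampling error of the slope. Genes are not independent replicates, and each slope is below 1 in the arm that did not choose the genes. Choosing genes by their response in 1 arm can give such slopes even with equal responses. The slopes therefore do not show a weaker response in either arm.

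**Figure D1:**
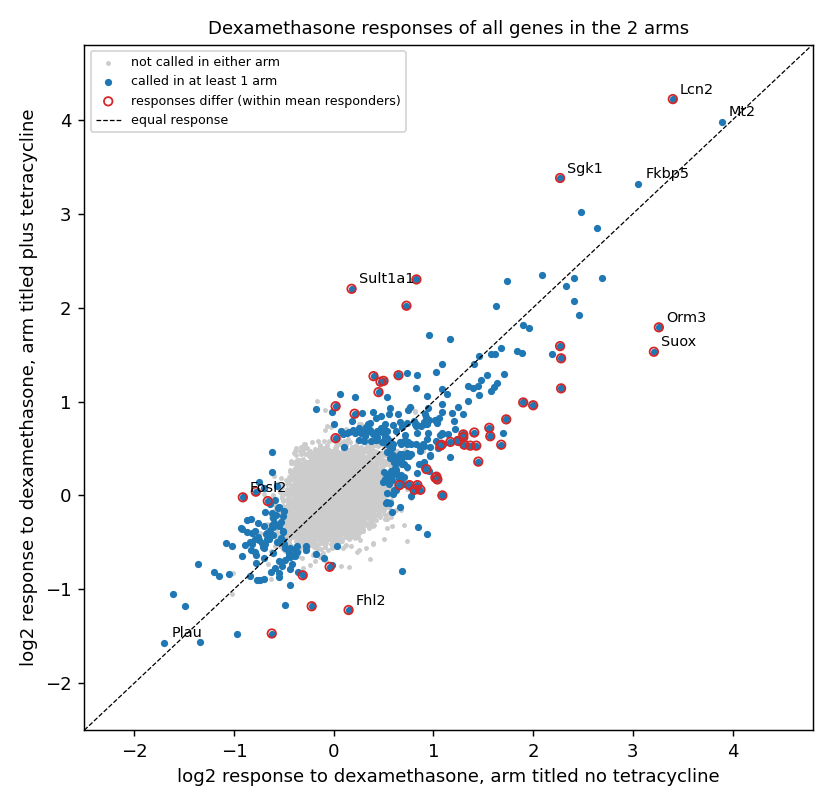
Log2 response to 4 h of dexamethasone for each gene, no-titled arm on the horizontal axis and plus-titled arm on the vertical axis. Blue points were called in at least 1 arm and red rings mark the 53 genes whose responses differ when adjusted over the responding genes alone. Mt2 and Fkbp5 lie near the dashed line of equal response, Suox and Orm3 below it, and Sult1a1 and Sgk1 above it.

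The hormone responses of the arms were compared by the difference of these responses, which does not separate AP-1 from other differences between the arms. Suox rose by 3.21 (9.28-fold) in the no-titled arm and by 1.53 (2.88-fold) in the plus-titled arm, a difference of -1.69 ± 0.15 (log2, SE; 95% interval -2.03 to -1.35; limma adjusted p = 0.00779). Its level moved from 5.81 ± 0.02 to 9.03 ± 0.11 in the former and from 6.03 ± 0.04 to 7.55 ± 0.07 in the latter (SD, n = 2). Suox was the 1 gene called of 19938, and its call was lost in 6 of the 8 fits without 1 array, at adjusted p up to 0.0843. An unadjusted p under 0.05 was reached by 1018 genes, against 997 by chance.

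The next genes by p missed the threshold over all genes. Sult1a1, which encodes a sulfotransferase, had responses of 0.18 in the no-titled and 2.20 in the plus-titled arm (difference 2.02 ± 0.26, adjusted p = 0.126). Orm3 had responses of 3.26 and 1.79 (adjusted p = 0.129), and Fhl2 had 0.15 and -1.22 (adjusted p = 0.129). Sgk1 responded by 2.27 and 3.38 (adjusted p = 0.129), starting from 7.71 ± 0.10 and 6.69 ± 0.09 and reaching 9.98 ± 0.11 and 10.07 ± 0.13. Abhd2 responded by 1.43 and 0.53 (adjusted p = 0.197). Adm had 0.94 and -0.41 (adjusted p = 0.129), Macroh2a2 0.69 and -0.80 (0.129), Dipk2a -0.62 and 0.46 (0.129) and Nr1h4 0.85 and -0.34 (0.158). The adjustment described next did not cover these last 4 genes, whose responses have opposite signs and were not called for their mean. When the adjustment covered only the 590 genes called for the mean of the 2 responses, a choice made after the data were seen, limma called 53 genes. Of these, 35 had the larger response in the no-titled arm and 18 in the plus-titled arm, and Suox, Sult1a1, Orm3, Fhl2, Sgk1 and Abhd2 were among them. Without 1 of the no-titled arm's own 4 arrays it called 26 to 34, and without 1 of the plus-titled arm's 39 to 57. In those fits the groups are unequal, so the mean response that selects genes is not independent of the difference tested. Of the lists, immediate-early genes (median 0.10, camera adjusted p = 0.0231), G1/S genes (median -0.22, adjusted p = 0.0231) and cholesterol synthesis genes (median -0.23, adjusted p = 0.0187) differed by camera. Each had adjusted p = 0.902 with an estimated correlation. Among members, 0 were called over all genes, and adjusted over the list alone 1 immediate-early gene and 0 of the others were.

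**Figure D2:**
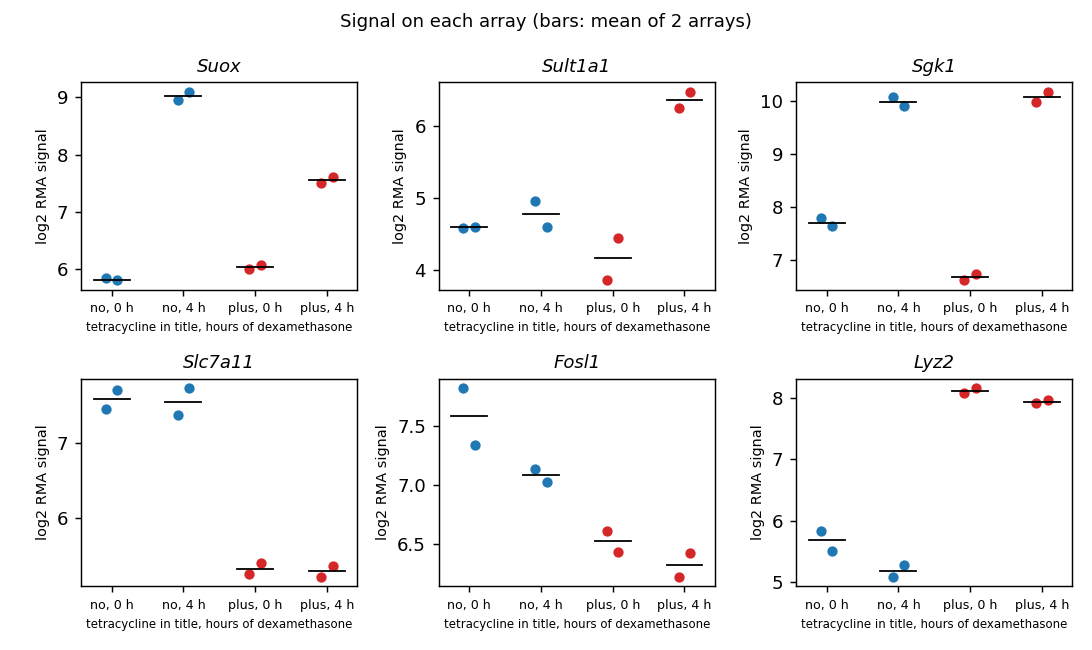
Log2 RMA signal of 6 genes on each of the 8 arrays, by the tetracycline state in the title and the hours of dexamethasone, with bars at the mean of 2 arrays. Suox reached 9.03 at 4 h in the no-titled arm and 7.55 in the plus-titled arm, and Lyz2 and Slc7a11 differed between the arms at both times.

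Without hormone the arms differed in named stress response, sterol and cell cycle genes. In the plus-titled arm Slc7a11, the cystine transporter gene of the integrated stress response, was lower at -2.27 ± 0.15 (log2, SE; adjusted p = 2.92e-05). Aldh1l2, a mitochondrial folate enzyme gene, fell by 1.94 and Trib3 fell by 1.18. Of the cholesterol synthesis genes, Lss was higher by 1.21 ± 0.14, Idi1 by 1.16 and Nsdhl by 1.11. Myc fell by 1.45, Plk2 fell by 1.84 and Lox fell by 1.64. Lyz2, which encodes a lysozyme, rose by 2.44 ± 0.13, Aldh1a1, a retinaldehyde dehydrogenase gene, by 2.36, Txnip by 2.00 and Gstm5, a glutathione S-transferase gene, by 1.97. Aldh1a1 and Aldh1a7, and the Gstm genes, are close relatives whose probes can read each other.

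Of 16 integrated stress response genes, 11 fell and 5 did not pass, and 13 fell when adjusted over the list alone (median -0.84, camera adjusted p = 1.18e-14, and adjusted p = 0.252 with an estimated correlation). Of 15 cholesterol synthesis genes, 14 rose, and all 15 when adjusted over the list alone (median 0.84, camera adjusted p = 7.19e-15, and adjusted p = 0.252 with an estimated correlation). G1/S genes fell in 13 of 20 cases, and in 14 when adjusted over the list alone (median -0.51, camera adjusted p = 7.87e-12, and adjusted p = 0.276 with an estimated correlation). Mcm7, a replication helicase gene, fell by 0.69. G2/M genes fell in 10 of 21 cases, and in 19 when adjusted over the list alone (median -0.42, camera adjusted p = 9.13e-11, and adjusted p = 0.276 with an estimated correlation). Of 17 interferon-stimulated genes, 5 rose, and 7 when adjusted over the list alone (camera adjusted p = 0.00623, and adjusted p = 0.252 with an estimated correlation), with Ddx58, an RNA sensor gene, at 0.83. Of 11 YAP-TEAD target genes, 4 rose and 1 fell, and 6 and 1 when adjusted over the list alone (camera adjusted p = 0.00623, and adjusted p = 0.276 with an estimated correlation), with F3 at 0.83 and Lats2 at 0.74. Of 21 matrix genes, 1 rose (Thbs1, 1.23) and 5 fell, and 1 and 6 when adjusted over the list alone (camera adjusted p = 0.0114, and adjusted p = 0.367 with an estimated correlation). Of 16 clock genes, 1 rose and 4 fell, and 1 and 5 when adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.252 with an estimated correlation), with Nfil3 at -1.27.

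The number of calls at 0 h depended on single arrays in some lists and held in others. Over the 8 fits without 1 array, the integrated stress response genes had 10 to 11 calls, the matrix genes had 1 higher and 5 lower in each, and the basal list had 0 to 1 higher and 1 lower. Its higher member, Acta2 at 1.66, was lost in 3 of these fits (adjusted p up to 0.175). These are counts, and the genes called may differ between fits. The cholesterol synthesis genes had 4 to 13, the G1/S genes 1 to 12, the G2/M genes 1 to 14 and the interferon-stimulated genes 1 to 4. The YAP-TEAD target genes had 3 to 5 higher and 0 to 1 lower, and the clock genes 0 higher and 1 to 3 lower. Among lists not called by camera, the glucocorticoid-induced genes had 0 to 3 higher and 1 to 3 lower, the inflammatory mediators 0 to 3 and 0 to 1, the AP-1 target genes 0 to 1 and 2 to 3, and the AP-1 subunit genes 0 to 1 higher with 2 lower throughout. The MAPK feedback genes had 0 to 2 higher, and the immediate-early genes 0 to 2 higher and 1 to 2 lower. The 1 lower gene among the receptor, its cofactors and chaperones, Fkbp4 at -0.43, was lost in 4 of the 8 fits.

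Among AP-1 genes, Fosl1 fell by 1.06 ± 0.16 (adjusted p = 0.00274) and Fosl2 fell by 0.76, and of 15 AP-1 subunit genes 1 rose and 2 fell, as they did when adjusted over the list alone (camera adjusted p = 0.472). Of 18 AP-1 target genes 1 rose and 3 fell, also when adjusted over the list alone, with Timp1 at -1.21 and a median of -0.06 (camera adjusted p = 0.0657). Fry, which asks whether members move one way on balance, gave a lower direction for the AP-1 target genes (adjusted p = 0.0223) and the AP-1 subunit genes (adjusted p = 0.0437). Of the target genes 5 lay above 0 and 13 below, while of the subunit genes 7 lay above and 8 below, with a median of -0.01. Jun at -0.01 and the receptor gene Nr3c1 at 0.05 did not pass. Of 16 genes of the receptor, its cofactors and chaperones, 1 fell, also when adjusted over the list alone (camera adjusted p = 0.703). Glucocorticoid-induced genes rose in 3 cases and fell in 3 of 29, also when adjusted over the list alone, with Sgk1 at -1.02 (camera adjusted p = 0.863). Inflammatory mediators had 3 higher and 1 lower of 25, and 3 and 2 when adjusted over the list alone (camera adjusted p = 0.761). MAPK feedback genes had 2 higher of 12, and 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0609). Immediate-early genes had 1 higher and 2 lower of 22, and 2 and 3 when adjusted over the list alone (camera adjusted p = 0.581). Among markers of other cells, Krt14 of the basal list fell by 1.39 and Lyz2 of the leukocyte list rose. The basal list had 1 higher and 1 lower of 8, also when adjusted over the list alone (camera adjusted p = 0.592). The leukocyte list had 1 higher of 10, also when adjusted over the list alone, with a median of -0.06 and a mean of 0.16 (camera adjusted p = 0.993). None of the 6 milk protein genes, 11 luminal, 7 adipocyte, 8 endothelial or 9 corticotroph markers was called by limma, over all genes or adjusted over the list alone, and camera adjusted p-values were 0.637, 0.346, 0.195, 0.592 and 0.592.

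Limma called 1870 genes at 0 h, 1236 higher and 634 lower in the plus-titled arm (66.1% higher, against 56.8% after cyclic loess and 74% after median centring), with 107 and 40 at least 2-fold. Without 1 array of these groups, the count was 589 and 677 (no-titled replicates 1 and 2) or 1311 and 1172 (plus-titled replicates 1 and 2). Of the 1311, 762 were higher and 549 lower.

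**Figure D3:**
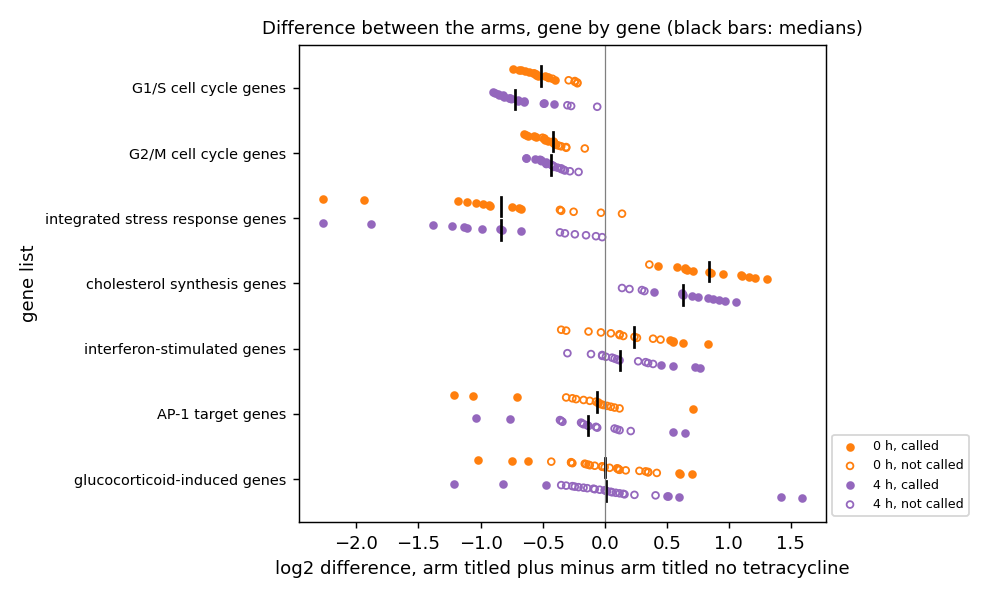
Log2 difference between the plus-titled and the no-titled arm for each member of 7 gene lists, at 0 h (orange) and at 4 h of dexamethasone (purple). Filled points were called, open points were not, and black bars are medians, which lie at -0.84 for the integrated stress response genes at both times and at 0.84 and 0.63 for the cholesterol synthesis genes.

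At 4 h of dexamethasone the arms differed in named stress response, sterol and cell cycle genes. Slc7a11 differed by -2.27 ± 0.15 (log2, SE; adjusted p = 5.67e-05), Aldh1l2 by -1.88, Trib3 by -1.38 and Shmt2, another mitochondrial folate gene, by -1.23. Lss, Nsdhl and Idi1 were higher by 0.97, 0.92 and 0.87. Lyz2 was higher by 2.75 ± 0.13, Klhl24 by 2.27 and Sult1a1 by 1.59. Il18rap was lower at -1.93, Suox at -1.47, Myc at -1.23 and Fabp4 at -1.35.

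Integrated stress response genes were lower in 10 of 16 cases, and in 12 when adjusted over the list alone (camera adjusted p = 2.22e-14, and adjusted p = 0.293 with an estimated correlation). Cholesterol synthesis genes were higher in 11 of 15 cases, also when adjusted over the list alone (camera adjusted p = 9.12e-11, and adjusted p = 0.293 with an estimated correlation). G1/S genes were lower in 15 of 20 cases, and in 18 when adjusted over the list alone (median -0.72, camera adjusted p = 1.54e-15, and adjusted p = 0.293 with an estimated correlation). Examples are Mcm2 at -0.90 and Cdt1, a replication licensing gene, at -0.88. G2/M genes were lower in 6 of 21 cases, and in 18 when adjusted over the list alone (camera adjusted p = 3.48e-10, and adjusted p = 0.323 with an estimated correlation). The YAP-TEAD target, matrix and clock genes, called by camera at 0 h, missed the threshold at 4 h (camera adjusted p = 0.0572 each). They had 5 higher and 0 lower of 11, 1 higher and 5 lower of 21, and 0 higher and 2 lower of 16. Fry gave them adjusted p = 0.0432, 0.0286 and 0.0178. Interferon-stimulated genes were higher in 4 of 17 cases, and in 5 when adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.293 with an estimated correlation). Of those 4, Bst2 and Stat2 were lost in 4 of the 8 fits without 1 array, Irf7 in 3 and Ddx58 in 2, and without replicate 1 of the treated plus-titled group 0 were called. Over the same fits the integrated stress response genes had 10 calls in each, the cholesterol synthesis genes had 3 to 11, the G1/S genes 8 to 16 and the G2/M genes 1 to 11. AP-1 target genes had 2 higher and 2 lower of 18, and 2 and 4 when adjusted over the list alone, with Timp1 at -1.04 (camera adjusted p = 0.277, and a lower direction by fry at adjusted p = 0.0415), and over the 8 fits 0 to 2 higher and 1 to 2 lower. Fosl1 was lower at -0.76 ± 0.16 (adjusted p = 0.0129), a call lost without either treated no-titled array (-0.71, adjusted p = 0.0939, and -0.81, adjusted p = 0.051) and without replicate 1 of the treated plus-titled group (-0.66, adjusted p = 0.088). Of 15 AP-1 subunit genes, Fos was higher and Fosl1 lower, also when adjusted over the list alone (camera adjusted p = 0.75). Jun at -0.16 (adjusted p = 0.494) and Nr3c1 at -0.05 (adjusted p = 0.864) did not pass. Among the glucocorticoid-induced genes, Lcn2 was higher by 1.42 and Rgs2 lower at -1.21, with 5 higher and 3 lower of 29, and 6 and 3 when adjusted over the list alone (camera adjusted p = 0.75). Over the 8 fits 2 to 5 were higher and 1 to 3 lower.

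Limma called 1916 genes at 4 h, 1054 higher and 862 lower. Without 1 array of these groups it called 654 and 910 (no-titled replicates 1 and 2) or 1073 and 743 (plus-titled replicates 1 and 2). The differences at 0 h and 4 h, which share no arrays, had 748 higher and 410 lower genes in common. Independent lists would share 65.3 and 27.4, though the spread that each gene has in common over all arrays can raise the overlap. In opposite directions 3 genes were called.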

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

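All tests of explanations in this part were chosen after the results were seen, and most of the values they use had been seen by then.

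Suox responded less to dexamethasone in the plus-titled arm, by -1.69 on the log2 scale, in a test of the difference itself. With the adjustment over responding genes alone, 53 genes responded differently. In 50 simulated sets with equal responses, that procedure called a median of 0 genes and at most 1. Those sets had independent noise for each gene, with no correlation between genes and no differences between cultures or whole arrays. Few calls were therefore built in, and the simulation does not show that the 53 are free of such effects. Over the 8 fits without 1 array the Suox difference lay between -1.77 and -1.61, so its size did not hang on 1 array. Suox was picked for its small p, which needs close replicates, so that range had to be narrow and adds no support. A signal ceiling is argued against, since Suox read lower at 4 h in the arm with the smaller response, by -1.47 ± 0.11 (log2, SE). For 1 overall weaker response in the plus-titled arm, the rule was written after its count was seen. Its allowance for false calls leaves out effects of cultures or whole arrays. Within those limits, such a response does not account for all 53. Of them 18 responded more in that arm, against 2.65 false calls allowed at the threshold. The fits without 1 array gave 8 to 23 such genes, between 28.6% and 41% of those called. Those fits share most of their arrays, so they add no independent support. A dependence of these genes on AP-1 binding was not tested by any of this and is only a hypothesis. Tetracycline itself or separate handling of the arms could also be the cause, and the design does not separate them. The sign of a dependence on AP-1 is open because the labels disagree on which arm expressed A-fos.

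Among the 53 genes, 32 differed between the arms at 4 h and were not called at 0 h, 10 were called at 0 h and not at 4 h, 8 at both times and 3 at neither. The responses of the immediate-early genes differed by a median of 0.10 by camera, those of the G1/S genes by -0.22 and those of the cholesterol synthesis genes by -0.23. Each had adjusted p = 0.902 with an estimated correlation, and 0 members were called by limma over all genes.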

How the results depend on the processing

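No called result of a named gene changed direction, but most settings could not have reversed one. Outside the difference of responses, the groups of every called gene did not overlap, so its sign holds without any 1 array. The other variance model, only the arrays compared, the block and the filter on dim genes leave the difference of group means unchanged. Only median centring, cyclic loess and the mean of probe sets could reverse a sign. Over 206 named gene results and 3067 alternative values, 2766 stayed on their side of the threshold, 286 lost the call and 15 gained it. Counts in the order of no-titled response, plus-titled response, arm difference at 0 h, at 4 h and difference of responses were 285, 220, 1870, 1916 and 1. Variance estimation with trend and robust settings gave 461 and 370 for the responses and 11 for their difference. Leaving out the dimmest 40% of genes gave 444, 357 and 6, with fewer genes tested. Median centring gave 2 for the difference of responses. The 2-fold minimum left 98, 69, 147 and 163. The adjustment over responding genes, chosen after seeing the data, gave 53. Ranges without 1 array, where the lone array is assumed to vary like the other groups, were 134 to 291, 80 to 187, 589 to 1642, 654 to 2128 and 0 to 2. Slopes between the responses moved from 0.746 to between 0.706 and 0.795, and from 0.89 to between 0.835 and 0.927. Camera called 27 pairs of list and contrast, and 2 with an estimated correlation, both of the glucocorticoid-induced genes. Fry, which does not compare a list with other genes, called 26 pairs, 3, 3, 10, 10 and 0 by contrast, with the stress response, cholesterol and cell cycle lists in both arm differences. The replicate number as a block gave 276, 222, 2028, 2108 and 1. Replicate differences correlated between groups at -0.019 to 0.133, and with 2 replicates the numbers do not pair the samples. With the block, Ccl2 in the no-titled response (adjusted p = 0.0642), Trib3 in the plus-titled response (0.0668) and Ier3 at 4 h (0.0546) were not called by limma, and the inflammatory mediators in the plus-titled response were not called by camera (adjusted p = 0.0618, and 0.127 without the dimmest genes). For other changes of counts the cause was not tested. No background signal was used here, so the genes too dim to change measurably were not counted.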

Other observations

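The 3 gene lists in this part and their tests, and those on Lyz2, the array and corticotroph RNA, were chosen after the results were seen, while the test of the labels was written before.

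Ribosome biogenesis genes were lower in the plus-titled arm, with 19 of 35 called lower at 0 h and 25 at 4 h, and 0 higher. FoxO target genes were higher in 10 cases and lower in 2 of 21 at both times, with Txnip at 2.00 at 0 h and Klhl24 at 2.27 at 4 h. This list also rose with dexamethasone, so it is not particular to the arm difference. In the no-titled response 5 were called higher and 1 lower (camera adjusted p = 0.000573, and 0.437 with an estimated correlation). In the plus-titled response 5 were higher and 0 lower (camera adjusted p = 6.56e-06, and 0.252 with an estimated correlation). Glutathione S-transferase and NRF2 target genes were higher in 4 cases and lower in 2 of 18 at 0 h, with Gstm5 at 1.97 and Slc7a11 at -2.27.

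The hypothesis that each list moved as a set was tested on the members whose values had not been seen when the lists were written. These members were read on the same arrays that prompted the lists. The estimated correlation between members was 0.549 for the full ribosome biogenesis list and 0.207 for the FoxO list. The test is therefore not independent of the choice of lists. The 32 such ribosome biogenesis genes had medians of -0.48 at 0 h and -0.70 at 4 h, and all 32 lay below 0 (camera adjusted p = 8.13e-15 and 1.47e-22, and adjusted p = 0.152 and 0.117 with an estimated correlation). The 18 FoxO target genes had medians of 0.25 and 0.31, with 8 called higher and 1 lower (camera adjusted p = 0.000158 and 6.68e-05, and adjusted p = 0.152 and 0.117 with an estimated correlation). Fry gave adjusted p = 0.0192 at 0 h and 0.00703 at 4 h for either list. Both are consistent with a move as a set, though neither passed against other genes with an estimated correlation. The 15 glutathione S-transferase and NRF2 target genes had medians of 0.09 and 0.06 (camera adjusted p = 0.302 and 0.0499, and adjusted p = 0.535 and 0.267 with an estimated correlation). Fry gave adjusted p = 0.176 and 0.0584, which leaves an activated NRF2 response open.

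The titles may carry the wrong tetracycline state, in which case the plus-titled arm expressed A-fos. Lower AP-1 target genes there were to count for this and higher ones against it. The list had a median of -0.06 at 0 h and camera adjusted p = 0.0657, which meets neither condition, and adjusted p = 0.276 with an estimated correlation. Fry, which asks only whether members move one way on balance, gave a lower list at adjusted p = 0.0223. The 2 readings of the labels cannot be told apart by this test, since its value lies short of the threshold in either direction.

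The many differences between the arms at 0 h do not rest on the array with the lowest median, since 1311 genes were called without it, 1078 of them among the 1870, and the 4 h difference uses other arrays. Corticotroph RNA in 1 arm was considered because the extraction text also names the pituitary line AtT-20. To cause these differences it would have to move its markers at least as far as the called genes, whose median size was 0.59 at 0 h and 0.60 at 4 h. The 9 markers had medians of -0.07 and 0, with an SD between markers of 0.12 and 0.17, the largest being -0.29 (Neurod1, 4 h), and Pomc stayed at or below 5.17 in every group. That argues against it as the cause, while a share too small to move these markers is not excluded. An effect of tetracycline itself, of A-fos, or of separate handling of the arms could each give 1870 differences (1311 without that array), and the design does not separate them.

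Lyz2 was higher in the plus-titled arm by 2.44 and 2.75, reaching a level of 8.12. The other 9 leukocyte markers had medians of -0.08 at 0 h and -0.18 at 4 h, and 0 were called. The SE of their mean across markers, which are not replicates, was 0.05 and 0.06. Ptprc stayed at or below 4.03 and Cd68, the highest of the 9, at or below 5.38 in every group. Macrophages or other leukocytes in a share large enough to move these markers are argued against. The markers are dim, where small folds are compressed, so a share too small to move them is not excluded. Shared probes with the related gene Lyz1 were not tested, and no biological explanation was tested.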
